A study of Drosophila melanogaster with 2 samples.

How the data were processed

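Whole embryos of a transgenic line expressing Sox102F with a C-terminal GFP were studied by ChIP-seq with an anti-GFP antibody, in 2 biological replicates of 1 group, per the labels. Chromatin was sheared by sonication, per the labels. The replicate numbers 2 and 3 were taken from the labels, and the stage of 12 to 14 h from the source name, since the age field held a number of hours that no embryo could have. Although the antibody field names Sox102F, the description states that the antibody was against GFP.

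The authors deposited peak lists in narrowPeak format on dm6, and the file lists deposited with them give how each was derived. Per these file lists, each replicate's peaks came from its alignments and a control file, the pooled peaks from the alignments of both replicates and the same control file, and the optimal IDR list from the replicate lists and the pooled list. The control itself was not analysed here, and the aligner, the peak caller and their versions are not given in the sources used here. The deposited lists give each peak an interval, a summit, a signal value and the −log10 of a q-value, the latter 2 as the narrowPeak format defines them. The signal value is the authors' score of a peak with no depth scaling stated, so it was used only to describe, rank or filter peaks within a list. The authors' −log10 q-value was capped at the maximum of each list and was constant at 4.18 over the whole optimal list, so it was not used for ranking. The deposited lists of replicate 2, replicate 3 and both pooled each ended at exactly 30000 peaks, so their weakest peaks depend on that limit.

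The optimal list was found to be exactly the 7488 peaks with the highest signal values of the pooled list. A comparison list of as many of the highest pooled peaks was therefore identical to it by construction and tested nothing. In the optimal list 74 rows repeated the interval of another row and 3 had a summit outside their own interval. All 7488 rows were counted as peaks. Whether these 3 were the summits found in a peak of neither replicate was not examined. No read counts were in the lists, so depth was unknown, and no limit from depth could be given. Regions of repeated sequence can lack peaks because reads there are not placed uniquely, and how such reads were treated is not given in the sources used here.

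Peaks were placed on the Ensembl release 115 annotation and the RefSeq sequence of Drosophila melanogaster, whose arm names matched and whose arm lengths held every peak. The arms 2L, 2R, 3L, 3R, 4, X and Y were used, and densities were taken over bases other than N. Each summit was given the first class that applied among promoter (within 500 bp of a TSS of a protein-coding gene), 5′ UTR, CDS, 3′ UTR, intron, genes that do not encode proteins and intergenic. Random expectations came from 1000 placements of as many points on the same arms, with the one-sided share doubled as p and 0.002 as the smallest possible raw value. A gene was called promoter-bound when an optimal summit lay within 500 bp of any of its TSSs. Replicate lists were compared by overlap of at least 1 bp or by the summit lying in a peak, and top lists against 100 random placements.

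Gene lists were tested by Fisher's exact test against all other protein-coding genes on the 7 arms, and in the alternative by gene body, from 1000 bp upstream to the gene end, against 10000 random lists matched on gene length in 10 classes. Of the genes in the lists 1 symbol, ATbeta, was not found in the annotation and was left out. Sequence words were counted on either strand within 50 bp of the summit and in windows of the same width 300 bp to either side. The exact sign test over peaks compared the centre with 1 flank per peak, picked at random. Ratios used both flanks, with a bootstrap of 1000 resamples. Signal values of promoter and distal peaks were compared by a permutation test of 100000 resamples on log2 signal values. Intervals of shares were Wilson intervals, and those of densities exact binomial intervals, at 95%. Families of tests were adjusted by Benjamini-Hochberg with a threshold of 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

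The tests, the 18 gene lists, the 21 sequence words, the rule for named genes and the other settings to be tried were fixed before the data were examined. Named were Sox102F, the 20 highest optimal peaks with their nearest genes, up to 4 bound members of each list that passed and up to 2 of each that did not, by promoter signal value, and the 5 genes with the most summits. The genes at 1 of the 20 highest peaks are not reported here. The remaining peaks of chromosome 4 were named after their values were seen, because they were few. These settings were the peaks above the median signal, each replicate alone with as many of its highest peaks as the optimal list held, other windows for promoters, distal peaks and small RNA genes, other rules of overlap, and other controls for sequence words. The measurement of base composition, random points matched on GC content (200 placements), dinucleotide shuffles and gene lists without chromosomes 4 and Y or without histone genes were added after the data were seen. The gene families defined by symbol were also set then, and the definition of the immune peptide genes was narrowed after its first result, since it had matched unrelated symbols.

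The tests were also run on simulated data, after their first use on the deposited lists rather than before it. With 7488 points of which a known part was placed at TSSs, a promoter share of 38.2% was recovered where 38.2% was true. The points left in place were counted by the same rule, and the moved points lay within the promoter window. This match was therefore fixed by construction and shows only that the count runs correctly. On random points 0 of 7 classes and 0 of 21 words passed. With AACAAT, set between G bases, planted in 9.51% of 7488 random windows the excess at the centre was 8.21 percentage points, since some windows already held the word, and 0 of 19 other words passed. The G bases were added after a first simulation without them, in which the planted word also raised the reversed Sox words by joining with neighbouring bases. Among 100 lists of 25 random genes 1 passed, and among 100 lists with a planted bound share of 50% 92 passed, over 13968 genes. The planted lists were adjusted together, which makes passing easier, and many of the real lists held fewer than 25 genes. The share recovered is therefore not the power of the real list tests, which may be lower. A planted log2 difference of 0.5 in signal was recovered as 0.49.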

Results

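Chromatin immunoprecipitation followed by sequencing was used to locate Sox102F in whole Drosophila melanogaster embryos at 12 to 14 h of age. Sox102F, a SoxD-family protein with a DNA-binding HMG box, carried green fluorescent protein at its C-terminus in a stable transgenic line, and chromatin was recovered with an antibody against GFP. The 2 samples were biological replicates of 1 group, numbered 2 and 3 in the labels, and no second group was analysed here. The comparisons were therefore between replicates, between classes of genomic sequence and between lists of genes. Each replicate list and the list from both replicates pooled held 30000 peaks. The optimal list, named for a test of reproducibility between replicates (IDR), held 7488, exactly the pooled peaks with the highest signal values. That test may have set their number, but not every one of them lay in peaks of both replicates. The optimal peaks had a median width of 298 bp and the authors' signal values from 97.2 to 4785. Read counts were not part of the peak lists, so the depth of each sample was unknown and intervals covered counting error of peaks or genes only. Coordinates are those of the dm6 assembly.

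Most of the highest peaks were shared by both replicates. Of the 7488 optimal summits, 7065 (94.4%, 95% Wilson interval 93.8 to 94.9%) lay in peaks of both replicates. Peaks of replicate 2 held 95.5% of the optimal summits, peaks of replicate 3 held 98.8%, and 3 summits lay in a peak of neither. Among the 500 highest peaks of replicate 2, 89.6% overlapped the 500 highest of replicate 3, against 0.23% when a list was placed at random on the same arms. The share was 87.8% for the 1000 highest (random 0.541%), 86.4% for the 2000 highest (random 0.932%) and 82.6% for the 5000 highest (random 2.09%). Over all 30000 peaks, 65.3% of those of replicate 2 overlapped a peak of replicate 3, and 66.8% in the other direction. Across the 7065 shared peaks, log2 signal values of the replicates gave a Pearson r of 0.891 and a Spearman rho of 0.853, where peaks are not independent replicates. Because the optimal list was derived from the replicate lists and the pooled list, its overlap with the replicate lists was not an independent estimate. With a reciprocal overlap of 50% of both peaks required, the share found in both replicates was 72.1%. The lists were called against the same control file, and the random placements could fall anywhere on an arm. Agreement between replicates therefore does not show that a shared peak is a site of the tagged protein.

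At the gene encoding the tagged protein, 1 optimal peak was found. Sox102F spans 800436 to 834393 on chromosome 4, on the minus strand, and the peak from 807382 to 807833 had its summit at 807618, inside the gene and 271 bp upstream of an internal transcription start site (TSS). Its signal value was 835, rank 494 of the optimal list, with 352 in replicate 2 and 494 in replicate 3. With a promoter window of 250 bp in place of 500 bp this peak no longer counted as a promoter peak.

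The highest signal value of the list, 4785, was at the promoter of CG14100 on 3L (19590388 to 19590858), 95 bp upstream of its TSS. The promoter of mRpL41, which encodes a protein of the mitochondrial ribosome, followed with 4778 on 2R (15217564 to 15218018). An intron of CG11050 on 2L (6612445 to 6612921) reached 4293, and the promoter of Ugalt, a UDP-galactose transporter gene, on X (2703667 to 2704107) reached 4086. The fifth peak, with 3988, lay on 2L (480867 to 481339) in an intron of ush, which encodes a cofactor of GATA factors, 1406 bp upstream of the nearest TSS, that of the zinc finger gene cbt. An intergenic peak on 2R, with CG13323 as the nearest gene at 11918 bp, had a signal value of 3913.

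Of the 20 highest peaks, 13 were at promoters, 5 in introns and 1 in intergenic sequence, and the peak nearest to CG4004 (3256) lay in a gene that does not encode a protein. Other promoters among them were those of px (3439), Art3 together with mRpS10 (3348), CG18549 (3326), and Tcs5 together with the ESCRT gene CHMP2B (3285). They went on with Chro, a chromosomal protein gene, together with Ssl1 (3205), PNPase (3124), the Polycomb-group gene ph-p (3041), Fkbp14 (2955) and Tina-1 (2890). The remaining intronic peaks lay in CG32772 (3056), in the overlapping HMG-box genes HmgD and HmgZ (2928), and in the protein kinase gene Lk6 (2856). In replicate 2 the lowest rank of these 20 peaks was 21, and in replicate 3 it was 24.

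Binding was unevenly spread over the chromosome arms, with few sites on chromosome 4. The optimal list held 6 peaks on chromosome 4, or 4.51 per Mb (exact 95% interval 1.65 to 9.81), against 55.1 per Mb on the other arms, a ratio of 0.0818. These were the peak at Sox102F, a promoter peak of the semaphorin receptor gene PlexA (signal value 697), 3 intergenic peaks nearest to lgs (836), Asator (217) and zfh2 (467), and a peak in an intron shared by Zyx and apolpp (124). The X chromosome had 62.6 peaks per Mb (59.8 to 65.5), 2L had 60.9 (58.1 to 63.8), 3L had 59.0 (56.5 to 61.5), 3R had 53.8 (51.6 to 56.1) and 2R had 47.6 (45.2 to 50.1). No peak was listed on the Y chromosome, nor in the full lists of either replicate or of both pooled. Whether peaks could be called on Y at all was unknown, so its test is not a measure of binding. The exact two-sided binomial test against arm length, adjusted by Benjamini-Hochberg over 7 arms, gave p = 2.55e-23 for chromosome 4, 2.03e-81 for Y, 3.81e-08 for X, 1.06e-05 for 2L, 0.000642 for 3L, 1.53e-07 for 2R and 0.461 for 3R. The total length included Y and chromosome 4, which raises the ratios of the large arms. A test over the large arms alone was not run. The ratio for chromosome 4 was 0.164 without replicate 2 and 0.0954 without replicate 3. The ratio for X was 1.16 without replicate 2 and 1.14 without replicate 3, and both passed (adjusted exact binomial p = 1.56e-06 and 1.72e-05). In the full lists, which reach weaker peaks, it ranged from 0.969 in replicate 2 to 1.10 in replicate 3. The value in replicate 2 passed as a deficit (adjusted exact binomial p = 0.0439), so the excess was not shared by every list.

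Promoters were the class of sequence with the largest excess of summits, and coding sequence the class with the largest deficit. Within 500 bp of a protein-coding TSS lay 2053 of the 7488 optimal summits (27.4%, Wilson interval 26.4 to 28.4%), against 11.5% ± 0.374 (SD over 1000 placements) of random points on the same arms, or 2.39-fold. Introns held 48.2% of the summits against 39.3% ± 0.575 of random points. Coding sequence held 15 summits (0.20%, interval 0.121 to 0.330%) against 13.9% ± 0.397, and 3′ UTRs held 0.788% against 4.54% ± 0.246. Intergenic sequence held 20.4% against 27.8% ± 0.506, 5′ UTRs 0.521% against 0.796% ± 0.103, and genes that do not encode proteins 2.5% against 2.20% ± 0.165. The two-sided permutation test, adjusted by Benjamini-Hochberg over 7 classes, gave p = 0.0028 for promoter, coding sequence, 3′ UTR, intron and intergenic sequence, whose raw p of 0.002 was the smallest the placements can give, then 0.00466 for 5′ UTR and 0.0719 for genes that do not encode proteins. When the random points were also matched on GC content, a choice made after the data were seen, promoters remained at 2.38-fold, introns stood at 1.09-fold in place of 1.23-fold, coding sequence held 0.0734 times its random share in place of 0.0144 and 3′ UTRs 0.0962 times in place of 0.174, and the 5′ UTR deficit no longer passed (0.949-fold, adjusted permutation p = 0.796). Genes that do not encode proteins passed with a promoter window of 250 bp (1.19-fold, adjusted permutation p = 0.00799) and of 1000 bp (1.15-fold, adjusted permutation p = 0.046).

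**Figure D1:**
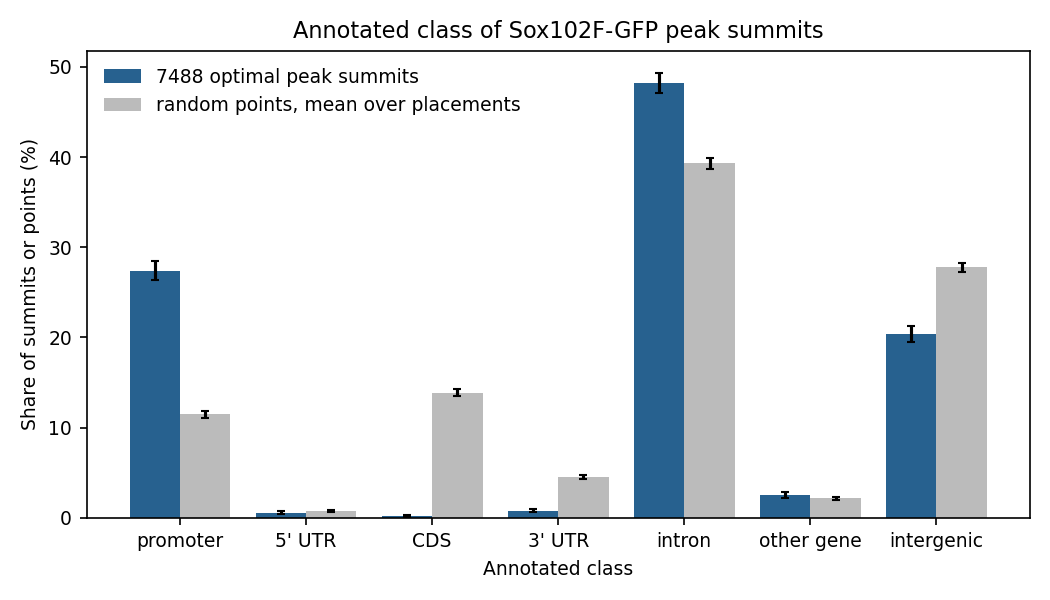
Share of 7488 optimal peak summits (blue, bars are 95% Wilson intervals) and of random points on the same arms (grey, mean of 1000 placements, bars are SD) in each annotated class, in percent. Promoters held 27.4% of summits against 11.5% of random points, and coding sequence (CDS) 0.20% against 13.9%.

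By these summits, 2362 of 13968 protein-coding genes (16.9%, Wilson interval 16.3 to 17.5%) were promoter-bound. Of the 2053 promoter peaks, 604 (29.4%) lay within 500 bp of the TSSs of 2 or more genes. Without replicate 2 the count of promoter-bound genes was 2843, of which 2204 were among the 2362, and without replicate 3 it was 2184, of which 1995 were among them.

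Ribosomal protein genes were more often promoter-bound than other genes, and histone genes were not bound at all. Of 92 ribosomal protein genes, 31 were bound (33.7%, Wilson interval 24.9 to 43.8%) against 16.8% of the other protein-coding genes, an odds ratio of 2.52. Their highest promoter peaks were at RpL34b (signal value 878), RpS27 (666), RpS20 (643) and RpL7 (569). None of 111 histone genes was bound, against 17.0% of other genes. Fisher's exact test, two-sided and adjusted by Benjamini-Hochberg over 18 lists, gave p = 0.00102 for ribosomal protein genes and 3.41e-08 for histone genes. The ribosomal protein list no longer passed among the optimal peaks above the median signal (odds ratio 2.00, adjusted exact p = 0.115). The histone genes are near-identical copies, in a cluster on 2L from 21416953 to 21541681 that held 0 pooled peaks, so their value is uncertain.

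The 16 other lists, of signalling pathways, patterning genes and markers of embryonic tissues, did not pass the test, with adjusted p from 0.181 to 1. The Notch pathway came nearest, with 7 of 19 genes bound (raw p = 0.0301, adjusted exact p = 0.181), among them E(spl)m3-HLH (signal value 937) and E(spl)m7-HLH (582), which encode transcriptional repressors. Within the promoter window of 250 bp its odds ratio fell from 2.87 to 0.849. Of the Sox family, 3 of 8 genes were bound (adjusted exact p = 0.627), Sox14 with a signal value of 1592, Sox102F and Sox100B. The Wnt pathway had 6 of 28 genes bound (adjusted exact p = 0.818), with the corepressor gene gro at 1395 and the kinase gene sgg at 1210. The EGFR and FGF pathways had 5 of 20 (adjusted exact p = 0.777), with the ligand gene spi at 1159 and aos, which encodes an inhibitor of EGFR, at 608. The Dpp pathway had 3 of 16 (adjusted exact p = 1), with shn at 142 and the receptor gene tkv at 135. Of 8 Hox genes only Antp was bound at a promoter, at 107 (adjusted exact p = 1).

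None of the lists of neuronal, neuroblast and glial genes passed the test. Neuronal differentiation genes had 2 of 27 bound (7.41%, Wilson interval 2.06 to 23.4%, adjusted exact p = 0.776), elav, which encodes a neuronal RNA-binding protein, at 1372 and the adhesion gene Fas2 at 138. Neuroblast and neural precursor genes had 3 of 25 bound (adjusted exact p = 1), with numb at 591 and grh at 211. Glial genes had 4 of 15 bound (adjusted exact p = 0.776), with moody at 895 and Gli at 433. Each of these odds ratios turned under another setting, that of neuronal genes from 0.393 to 1.09 with the 1000 bp window, that of neuroblast genes from 0.670 to 1.35 without replicate 3, and that of glial genes from 1.79 to 0.516 with the 250 bp window. When any summit in the gene body was counted and random lists were matched on gene length, 4 of 25 neuroblast genes (16.0%) held a summit against 39.7% in matched lists (adjusted permutation p = 0.0588). By the same count, 10 of 27 neuronal genes (37.0%) held a summit against 60.2% (adjusted permutation p = 0.0774).

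Among the markers of other tissues, 6 of 24 somatic and visceral muscle genes were bound (adjusted exact p = 0.776), with Msp300 at 1059 and sls, which encodes a giant sarcomere protein, at 863. Heart genes had 1 of 16 bound (adjusted exact p = 0.818), the homeobox gene tin at 787. Epidermis and cuticle genes had 3 of 18 bound (adjusted exact p = 1), with tyn at 301 and grh at 211, and tracheal genes 2 of 11 (adjusted exact p = 1), with trh at 626 and dysf at 255. Hemocyte and fat body genes had 2 of 16 bound (adjusted exact p = 1), Adh at 600 and ush at 313, and gut genes 2 of 13 (adjusted exact p = 1), bowl at 1265 and fkh at 230. Germ cell genes had 3 of 10 bound (adjusted exact p = 0.777), with piwi at 803 and gcl at 354.

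**Figure D2:**
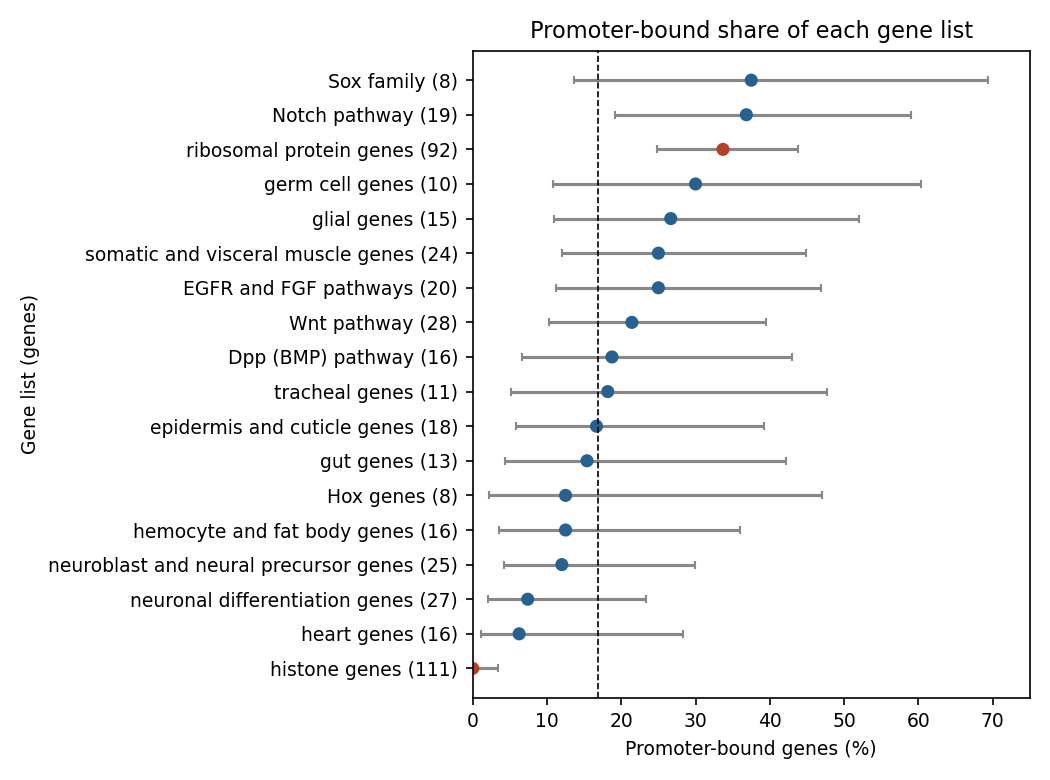
Share of promoter-bound genes in each of 18 gene lists, in percent, with 95% Wilson intervals and the number of genes in parentheses; the dashed line is the 16.9% of all protein-coding genes. The lists in red, ribosomal protein genes at 33.7% and histone genes at 0%, passed the adjusted test, and those in blue did not.

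Several long genes held many summits each, counted and divided by length with the 1000 bp upstream of the gene included. The gene with the most was kirre, which encodes an immunoglobulin-domain receptor of muscle founder cells, with 43 optimal summits in a gene of 394 kb on X, or 1.09 per 10 kb against 0.546 over the 7 arms. CG1677 (125 kb on X) held 22, or 1.75 per 10 kb, and CG43658 (105 kb on X) held 21, or 1.98 per 10 kb. The genes shn and ush each held 18, shn in a gene of 58.3 kb on 2R (3.03 per 10 kb) and ush in one of 64.3 kb on 2L (2.75 per 10 kb). Summits at other genes that lie inside these were counted too, such as w inside kirre and brk inside CG1677. These long genes were chosen for their number of summits, which grows with length, so no test was made of them.

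Sequence words of the Sox core were more frequent at the summits than in the flanks of the same peaks, and so were words of the same bases in reversed order. The short core ACAAT lay within 50 bp of 33.9% of the 7488 optimal summits, against 23.6% in flanking windows 300 bp away, a ratio of 1.44 (95% bootstrap interval 1.38 to 1.5). The extended core AACAAT lay at 15.4% against 10.1%, a ratio of 1.52 (1.41 to 1.64). The reversed words TAACA and TAACAA had the higher ratios of 1.80 (1.71 to 1.91) and 1.85 (1.70 to 2.01). The word ACAAAG, shared by Sox and TCF proteins, had a ratio of 0.990 (0.896 to 1.08) and the TCF word CTTTGA 1.24 (1.11 to 1.38). The exact two-sided sign test over peaks, adjusted by Benjamini-Hochberg over 21 words, gave p = 1.2e-49 for ACAAT, 6.63e-28 for AACAAT, 4.6e-83 for TAACA and 1.71e-38 for TAACAA.

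Among words of other proteins, those more frequent at the summits were made mostly of A and T, and those less frequent held more G and C. The DRE word TATCGATA had a ratio of 2.32 (adjusted exact p = 0.000151), the homeodomain word TAATTA 2.16 (1.29e-48), the Mef2 word 2.14 (0.00183) and the GATA word AGATAA 1.75 (3.98e-21). The GAGA word had a ratio of 0.185 (3.36e-30), the CA repeat 0.239 (1.89e-55), the Su(H) word 0.380 (3.57e-10) and the Pho word 0.642 (9.49e-26). The E-box words CACCTG, CAGCTG and CACGTG had ratios of 0.450, 0.452 and 0.474 (adjusted exact p = 3.4e-15, 2.38e-18 and 3.24e-06), and the Grainyhead word 0.681 (0.0146). The words of Zelda (0.561, adjusted exact p = 0.173), AP-1 (0.814, 0.453) and Motif 1 (0.963, 0.851) did not pass. The DRE word no longer passed among peaks above the median signal (1.3, adjusted exact p = 0.165), among distal peaks (2.75, 0.221) or against pooled peaks outside the optimal list (1.37, 0.125). The Mef2 word no longer passed among peaks above the median signal (1.91, adjusted exact p = 0.145), among distal peaks (2.00, 0.126), without replicate 3 (1.58, 0.277) or in a window of 100 bp either side (1.33, 0.0568). The Grainyhead word no longer passed in the first 3 of these (0.685, 0.677 and 0.705, adjusted exact p = 0.111, 0.0765 and 0.0623) or against the pooled peaks (0.947, 0.735). Among distal peaks alone the words of Zelda (0.577, adjusted exact p = 0.0469) and Motif 1 (6.0, 0.00547) passed. These words were rare, at 0.307% and 0.174% of all optimal summits.

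**Figure D3:**
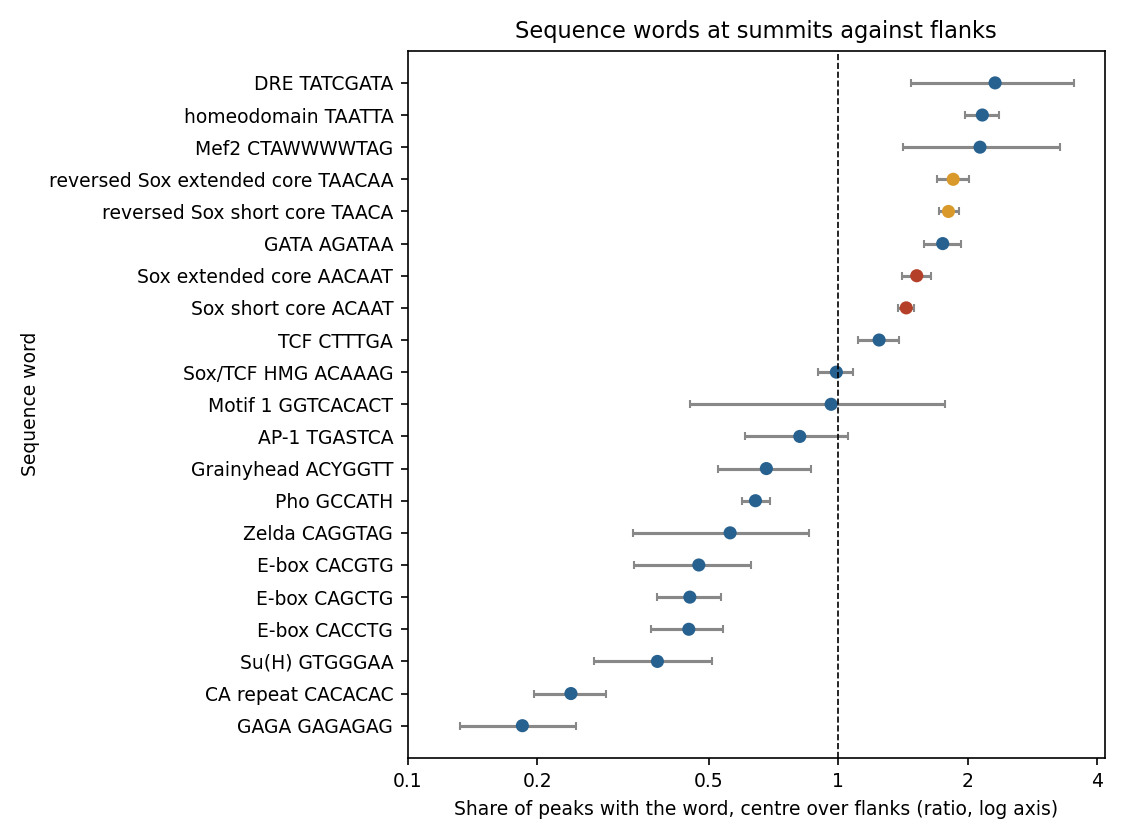
Share of optimal peaks with a sequence word within 50 bp of the summit, divided by the share in flanking windows 300 bp away, on a log axis with 95% bootstrap intervals. The Sox cores (red) had ratios of 1.44 and 1.52, below the reversed words of the same composition (orange) at 1.80 and 1.85.

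Base composition changed sharply at the summits themselves, as measured after the word counts were seen. Within 50 bp of the optimal summits 30.6% ± 8.14 (SD over 7488 peaks) of bases were G or C, against 44.5% ± 7.0 in the flanks 300 bp away, and 87.6% of the peaks had the lower value at the centre. The median difference was -15.3 percentage points (bootstrap interval -15.3 to -14.9). It was -14.9 points at promoter summits, -15.3 at distal summits over 1000 bp from any TSS, -2.97 at the pooled peaks that do not overlap the optimal list and 0 at random points. When each central window was instead compared with 5 shuffles that keep its dinucleotides, ACAAT (ratio 0.907, adjusted exact p = 4.57e-07) and AACAAT (0.916, adjusted exact p = 0.0401) were less frequent than in the shuffles. So were the reversed words TAACA (0.860, adjusted exact p = 1.04e-11) and TAACAA (0.882, 0.0223) and the homeodomain word (0.790, 1.56e-09), each of which had been more frequent than in the flanks. The words DRE (3.10, adjusted exact p = 0.00138), Motif 1 (8.13, 0.00549), CAGCTG (2.13, 3.7e-08), GAGA (1.92, 0.0163) and the CA repeat (2.04, 1.48e-06) were more frequent than in the shuffles, the last 3 having been less frequent than in the flanks. Motif 1 lay at only 0.174% of summits (bootstrap interval of the ratio 3.33 to 23.8) and the DRE word at 0.588%, so these ratios rest on few peaks. The remaining words did not pass against the shuffles, Mef2 (1.12, adjusted exact p = 0.0647) and GATA (0.866, 0.0625) among them. The ratios used all 5 shuffles of each window, but the exact test used only the first. Ratio and test can therefore differ, as for GATA (bootstrap interval 0.797 to 0.937) and Pho (1.11, 1.03 to 1.19), whose intervals excluded equality.

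**Figure D4:**
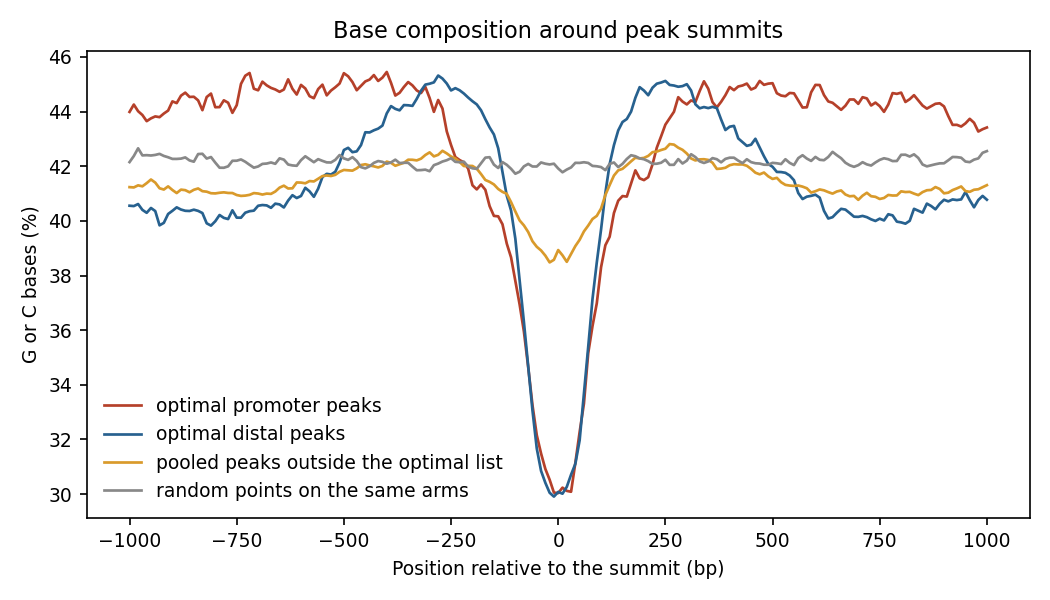
Mean share of G or C bases in percent against the position relative to the summit in bp, for optimal promoter peaks, optimal distal peaks, pooled peaks outside the optimal list and random points. At the summit the promoter and distal lines fell to 30.04% and 30.08%, against 38.9% for pooled peaks outside the optimal list and 41.9% for random points.

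Promoter peaks had higher signal values than distal peaks. The median signal value was 266 over 2053 promoter peaks and 184 over 4721 distal peaks, a difference of 0.54 on the log2 scale (bootstrap interval 0.47 to 0.61). The permutation test, two-sided with 100000 resamples, gave p = 1e-05, the smallest it can give, with peaks as the units, which are not independent replicates. In the fifth of the list with the highest signal values 43.9% of the summits were at promoters, and in the fifth with the lowest 19.1%.

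Small RNA genes, a class that often gives signal in ChIP whatever the target, did not pass the test in either direction. A summit lay within 250 bp of 9 of 290 tRNA genes (3.10%, Wilson interval 1.64 to 5.79%; 1.01-fold against random points, adjusted permutation p = 1). It was 4 of 32 snRNA genes (12.5%, 4.97 to 28.1%; 3.22-fold, adjusted permutation p = 0.105) and 2 of 269 snoRNA genes (0.743%, 0.204 to 2.67%; 0.228-fold, adjusted permutation p = 0.105). The values rested on few genes: without replicate 2 the snRNA genes passed at 4.11-fold (adjusted permutation p = 0.030), and without replicate 3 none was bound. Without replicate 3 the snoRNA genes passed at 0.113-fold (adjusted permutation p = 0.048), and without replicate 2 they stood at 0.340-fold.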

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

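The comparisons with random points matched on GC content, with dinucleotide shuffles, of base composition and of gene lists without chromosomes 4 and Y or without histone genes were chosen only after the results were seen. No paired analysis was possible because the samples form 1 group. The promoter excess kept its direction and passed under every other setting run, from 1.82-fold with a 1000 bp window to 2.98-fold among peaks above the median signal, and so did the deficit of coding sequence (0.00576 to 0.0734 times random), the deficit of chromosome 4 (ratio 0.0510 in the full pooled list to 0.164 without replicate 2) and the higher signal of promoter peaks (0.40 to 0.53 on the log2 scale). The count of promoter-bound genes ranged from 1618 to 2903. The counts that follow leave out promoters, coding sequence and the words ACAAT and AACAAT. Among values of the other single lists, classes, words and named peaks, 293 kept their direction and side of the threshold, counting the list identical by construction. Direction turned for 42, among them Motif 1, which came to pass among distal peaks and against shuffles. A further 17 kept their direction but no longer passed. Another 3 came to pass in the same direction (genes that do not encode proteins with both other promoter windows, and Zelda among distal peaks). Without a test, 1 value moved. The value that moved was the promoter peak of Sox102F, lost with the 250 bp window alone. Depth was unknown, so what it limits could not be given.

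The share of optimal summits found in both replicates moved to 72.1% with a reciprocal overlap of 50% and 93.0% with summits within 100 bp. The gene lists that passed fell from 2 to 1 among peaks above the median signal, a list with fewer peaks, and to 1 without histone genes, which takes away a list that had passed. The change of base composition moved to -16.3 points among peaks above the median signal, -13.9 in a wider window and -2.97 at pooled peaks outside the optimal list. Leaving out a replicate gave ratios of 0.969 and 1.00 for 3R, 0 and 4.11 for snRNA genes and 0.113 and 0.340 for snoRNA genes. In the full list of replicate 2 the ratio for 3R was 1.04 and passed (adjusted exact binomial p = 0.00239). In that of replicate 3 it was 0.993 (0.585).

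With dinucleotide shuffles as control the direction turned for ACAAT (0.907), AACAAT (0.916), TAACA (0.860), TAACAA (0.882), GAGA (1.92), the CA repeat (2.04), Zelda (1.06), CAGCTG (2.13), CACCTG (1.07), GATA (0.866), homeodomain (0.790), Motif 1 (8.13), Su(H) (1.16), AP-1 (1.19) and Pho (1.11). This control keeps the composition of the central window, which the flanks do not share. Motif 1 also turned with a window of 100 bp either side (1.61), among distal peaks (6.0) and without replicate 2 or 3 (1.06 and 1.73), and ACAAAG among distal peaks (1.01) and between the replicates (0.980 and 1.00), where the cause was not tested.

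Odds ratios of lists that never passed crossed 1 under some settings, and the cause was not tested. With the 250 bp window these were Notch (0.849), EGFR and FGF (0.802), glial (0.516), muscle (0.314), epidermis (1.45), tracheal (0) and gut (1.31). With the 1000 bp window they were neuronal (1.09), epidermis (1.91) and tracheal (0.847), and among peaks above the median signal Dpp (0), hemocyte and fat body (1.09) and gut (1.39). By gene body the ratio of the share of genes with a summit to that of length-matched lists, not an odds ratio, lay on the other side of 1 for Sox family (0.827), Hox (1.13), muscle (0.932), epidermis (1.09) and gut (1.02). Leaving out a replicate gave odds ratios of 0.771 to 0.903 for Dpp, 0 to 1.80 for Hox, 0.533 to 1.35 for neuroblast and 0.782 to 1.08 for epidermis genes.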

Other observations

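All tests of this part were chosen only after the results they bear on were seen.

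Chemoreceptor, cuticular protein, immune peptide and digestive protease genes had few promoter peaks. Of 11 families defined by gene symbol, 4 were less often promoter-bound than other genes by Fisher's exact test with Benjamini-Hochberg adjustment, and 0 more often. The test took the genes of a family as independent, and how close together or alike in sequence they are was not examined. Chemoreceptor genes had 1 of 179 bound (adjusted exact p = 2.29e-12), which was Ir67c with a signal value of 104. Cuticular protein genes of the Cpr family had 3 of 70 (adjusted exact p = 0.0118), immune peptide genes 0 of 32 (adjusted exact p = 0.0144), and Jonah and trypsin protease genes 0 of 25 (adjusted exact p = 0.0411). Mitochondrial ribosomal protein genes had 20 of 73 (adjusted exact p = 0.0587), with mRpL41 at 4778, mRpS10 at 3348 and mRpS23 at 2784, and aminoacyl-tRNA synthetase genes 10 of 32 (adjusted exact p = 0.0982), with IleRS at 926. Cytochrome P450 genes (8 of 85), respiratory chain genes (12 of 80), proteasome genes (4 of 48), initiation factor genes (8 of 44) and Tim and Tom genes (1 of 15) had adjusted exact p from 0.125 to 0.840.

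Genes with a head-to-head neighbour, whose TSS lies within 1000 bp upstream on the other strand, were bound in 1291 of 5052 cases (25.6%) against 12.0% of other genes, an odds ratio of 2.51 (exact interval 2.30 to 2.75). A single promoter peak can count for both genes of such a pair, so these genes are not independent. Among words of 6 bases found at the centre of at least 5% of peaks, the highest ratio of centre to flank was that of ATATTA (3.97), and 10 of the 20 highest held only A and T. The change of base composition was -17.3 points in the fifth of peaks with the highest signal values and -12.9 in the fifth with the lowest.

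Summits lay in narrow stretches rich in A and T. The tables argue against the exact core words as the source. The centre-to-flank ratio of AACAAT was above those of only 10.3% of the 29 other words of its base composition. That of ACAAT was above those of 15.8% of 19 such words. The words compared with AACAAT include ACAATA (1.98), which itself holds ACAAT, so recognition of variant Sox sequences was not tested. Promoter composition was also argued against, since the change at distal summits was 1.03 times that at promoter summits (bootstrap interval 1.00 to 1.10). A library bias against GC-rich fragments stays open, since the reads and the control that would show it were not analysed here. No biological explanation was tested.

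Chromosome 4, which carries Sox102F itself, held 0.0797 times as many peaks per Mb as the other large arms (exact interval 0.0292 to 0.174). Repeats were argued against as the whole cause, since 28.1% of its bases were masked as repeats against 20.1%, and peaks per base outside them were still 0.0887 times those of the other large arms (exact interval 0.0325 to 0.193). A scarcity of AT-rich dips was argued against only for dips defined as at least as low in G and C and as far below their flanks as the median peak. Such dips occurred 790 times per Mb on chromosome 4 and 823 elsewhere, a ratio of 0.960 (exact interval 0.902 to 1.02). On the other large arms only 4.92% of them lay within 100 bp of an optimal summit. A scarcity of the narrower kind of dip that held peaks, such as dips within flanks of a given composition, was therefore not tested. Over all its bases chromosome 4 was lower in G and C, at 35.2%, against 41.6% to 42.6% on the other large arms. A scarcity of promoters was argued against as the whole cause, since the promoter-bound share of genes was 0.147 times that of those arms (exact interval 0.0178 to 0.531), below the ratio of 1 that scarcity alone would give although not wholly below the limit of 0.5 set for this first test, and the density of protein-coding genes, taken up after a second test whose outcome the number of peaks fixed, was 0.574 times theirs (exact interval 0.454 to 0.714). No biological explanation was tested, and the chromatin of this chromosome, known as partly heterochromatic, was not measured here.

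Ribosomal protein genes were promoter-bound more often than other genes. Head-to-head gene pairs were argued against as the whole cause, since among genes without such a neighbour the odds ratio was 3.12 (11 of 37 bound, exact interval 1.39 to 6.56), while among genes with one, which held 55 of the 92, it was 1.67 (exact interval 0.913 to 3.00, exact p = 0.0855) and did not pass. Whether promoters of housekeeping genes in general share some excess could not be told. Mitochondrial ribosomal protein, proteasome and respiratory chain genes together had an odds ratio of 1.07 with an interval from 0.725 to 1.55. This interval lay below the odds ratio of 2.52 of all ribosomal protein genes. The joint value mixed families that differed, however, from 27.4% bound for mitochondrial ribosomal protein genes to 8.33% for proteasome genes. No biological explanation was tested, and ribosomal protein genes are highly transcribed, which can raise ChIP signal whatever the target and stays open.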
